A study of Mus musculus with 6 samples.

How the data were processed

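RNA-seq was carried out on 6 libraries that the labels describe as hearts of mice given an AAV9 vector for FNDC4 overexpression (AAV9-hFNDC4, 3 libraries) or a control AAV9 vector (AAV9-CTRL, 3 libraries). AAV9 is an adeno-associated virus serotype that transduces the heart, and FNDC4 is a secreted factor with a fibronectin type III domain. Per the labels, all mice underwent ischemia/reperfusion (I/R), a temporary block of blood flow to the heart followed by its return, and tissue was taken 24 h later. RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. Whether RNA was selected by its poly(A) tail, and whether libraries kept strand, are not given in the sources used here.

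The authors deposited a table of raw read counts per gene symbol, with 1 column per library and no normalization. Trimming with fastp, alignment with HISAT2, counting with HTSeq and the use of R 3.2.0 and DESeq2 are named per the submitters' processing notes, with the mouse genome build GRCm38 (mm10). The parameters, the annotation release and the rule for reads that match several genes are not given in the sources used here. Near-identical copies such as Hspa1a and Hspa1b are therefore uncertain in how their reads were split. Without a stated strand setting, reads of a gene and of an overlapping gene on the other strand could not be told apart. Exon overlap was checked in the GENCODE vM21 basic annotation (GRCm38), in which 143 of 148 named genes were found. Of these, 32 shared exon bases with another gene and 11 shared at least 10% of their exon bases.

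Counts were analysed in R 4.3.3 with edgeR 4.0.16. Of 27482 gene symbols, 14663 passed the filterByExpr minimum with default settings. Library sizes were normalized by TMM, dispersions were estimated with robust settings, and the groups were compared with the quasi-likelihood F test. The adjusted p-value is that of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Means are given as CPM, the counts scaled by library size. Those per group, with the SD over 3 libraries, used library sizes normalized by TMM. Marker levels averaged over all 6 libraries, the most abundant transcripts and the 1 CPM limit for markers used plain library totals, so the 2 kinds of mean differ for the same gene. For genes at 0 in all 3 libraries of a group, the fold change was bounded against a floor of 3 counts over the group. For genes with 1 to 3 counts over a group, the ratio of counts is given with its exact 95% binomial interval. These floors and intervals cover counting error only, since PCR copies are not independent molecules.

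Before the data were examined, 33 gene lists (pathways, markers of cell types of the injured heart, and genes of other tissues), the rule for named genes and the alternatives below were fixed. Named were Fndc4, Hif1a, Vegfa, Fgf1, Adgrf5 and Epas1, and per direction the 12 genes with the largest change among those past the threshold, with groups that did not overlap, a mean of at least 1 CPM and no predicted-gene symbol. Also named were up to 4 members of each list with the smallest p, and more where a count of 5 or fewer was named in full. Fndc4 and Epas1 were not analysed here, and a few genes that the rule names are not reported here. Lists with at least 5 tested members, 27 in number, were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera with an estimated correlation, which allows for members that vary together, and fry, which tests whether the members of a list change, were run beside it. The marker genes whose levels describe the material were picked after their values had been seen. Lists of further cell types, of Y chromosome genes and of 6 other gene groups were chosen after the data had been seen, that of Y chromosome genes before their own levels were seen. Chromosome positions are those of the RefSeq annotation of GRCm38.p6.

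The alternatives were RLE size factors, upper-quartile normalization, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an unadjusted p under 0.05 with an absolute log2 fold change above 1, and leaving out each library in turn. Corrections for transcript length and GC content (a loess trend with a span of 0.4 per library, applied as offsets) were added after the data had been seen. The tests were run on simulated counts with 200 changed genes among 14663 and, besides them, the 17 tested glycolysis genes lowered 2-fold. The main test recovered 82% of genes changed 2-fold and 48% of genes changed 1.5-fold, with false calls at 0.09% of unchanged genes and 8.23% of all calls. The 200 changed genes were drawn from those above 1 CPM outside the lists, with as many raised as lowered. These rates therefore do not cover genes under 1 CPM, or data such as these, in which 47.1% of tested genes were called. With no change simulated, 0 of 27 lists were called. Genes were simulated independently of each other, so this does not test the preset inter-gene correlation on which the camera calls rest. A simulated length trend with a slope of 0.252 was reduced to 0.00275 by the length correction.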

Results

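Gene expression was measured in 6 RNA-seq libraries, 3 labelled AAV9-hFNDC4 and 3 labelled AAV9-CTRL, all from material labelled as mouse heart 24 h after I/R. Total counts lay between 34419687 and 35149915 in the libraries labelled AAV9-hFNDC4 and between 32975817 and 36074046 in those labelled AAV9-CTRL. At this similar depth, 18717 to 18863 genes had at least 1 count in the libraries labelled AAV9-hFNDC4, against 20431 to 20870 in those labelled AAV9-CTRL. The correlation of log2 CPM was 0.981 to 0.990 within groups and 0.938 to 0.952 between them. Nothing in the labels says that the libraries came from separate animals, so the p-values measure the spread between these libraries, which may be technical. All values after ± are SD with n = 3 libraries.

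Most transcripts that define heart muscle were nearly absent from the libraries. Myh6, the main myosin heavy chain of the adult mouse heart, averaged 0.276 CPM over the 6 libraries, Actc1 (cardiac actin) 0.0939, Tnni3 (cardiac troponin I) 0.180, Myl2 (ventricular myosin light chain) 0.501, and Nkx2-5 had no counts. Of 31 cardiomyocyte markers, 12 reached 1 CPM in at least 3 libraries, with a list median of 0.276 CPM, and the most abundant was Atp2a2 at 474 CPM, a calcium pump that many cell types express. Markers more restricted to muscle were also among the 12, with Tnnt2 (cardiac troponin T) at 44.6 CPM, Hspb7 at 21.8, Ldb3 at 20.6, the cardiac transcription factor Gata4 at 9.96 and Ttn (titin) at 4.28. Endothelial Cdh5 averaged 0.0283 CPM, the leukocyte surface marker Ptprc 0.0910 CPM and the macrophage marker Adgre1 0.0283 CPM. Of the endothelial markers, 8 of 21 reached 1 CPM, as did 1 of 7 markers of all leukocytes, 2 of 19 neutrophil, 1 of 14 lymphocyte, 11 of 22 monocyte and macrophage, 3 of 13 mural cell and 13 of 18 fibroblast markers. The most abundant transcripts included Eef1a1 (7826 CPM), Hspa5 (4051), Fn1 (3778), Vim (3569) and Spp1 (2963). Since these levels go against the tissue label, the groups are named by their labels throughout, and no change is assigned to heart muscle.

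**Figure D1:**
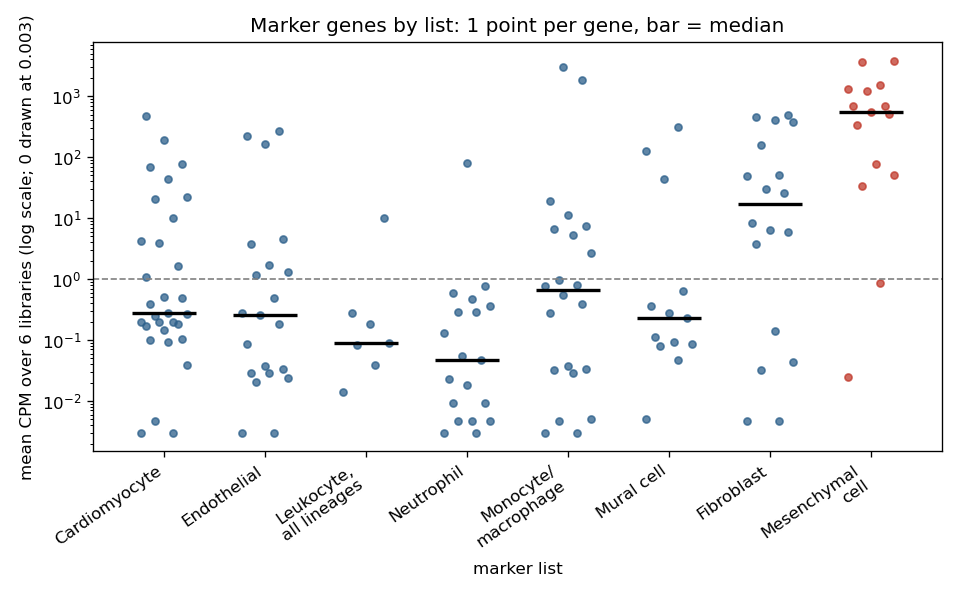
Mean CPM over the 6 libraries (log axis, values of 0 drawn at 0.003) of the measured members of 8 marker lists, with 1 point per gene, the list median as a bar and a dashed line at 1 CPM. The cardiomyocyte median lay at 0.276 CPM and the median of the mesenchymal list, written after abundant members had been seen, at 555 CPM.

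The comparison asked how expression differed between FNDC4 overexpression and control vector after I/R. In the libraries labelled AAV9-hFNDC4, genes of the heat shock response (Hspa1b, Hsph1, Bag3) and immediate early genes (Fos, Fosb, Egr1) were lower by 4.29-fold to 731-fold. Nuclear genes of oxidative phosphorylation were lower by a median log2 fold change of -0.72 (camera, Benjamini-Hochberg adjusted p = 7.8e-14, and adjusted p = 0.426 with an estimated correlation), which was -0.42 with the length correction. In contrast, Hif1a, its target Vegfa, the matrix gene Fn1 and the proliferation gene Mki67 were higher by 1.40-fold to 2.89-fold. These are single genes, since the lists of HIF1A targets, matrix genes and proliferation genes were not called (camera, Benjamini-Hochberg adjusted p = 0.0716, 0.866 and 0.789). Longer transcripts had higher fold changes, with a median log2 fold change of 0.44 in the longest 10%. Length-corrected values of these single genes are not given here, so a part that goes with length is not excluded. Of 14663 genes tested, 3240 were higher and 3668 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), together 47.1%. Changes of more than 2-fold were seen in 993 higher and 1053 lower genes, and changes of more than 8-fold in 17 higher and 297 lower genes. The groups did not overlap in 56.6% of tested genes, against 10% that chance gives for 3 against 3. Throughout, higher and lower refer to the libraries labelled AAV9-hFNDC4 relative to those labelled AAV9-CTRL. Fndc4, the overexpressed gene, was not analysed here, so the vector labels carry no check from it.

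The series title ties FNDC4 to HIF1A-dependent cell survival and angiogenesis. The values below are RNA levels, which do not measure HIF1A protein or its activity. Hif1a, the oxygen-regulated transcription factor subunit (chromosome 12, 73901324 to 73947554), was higher at 226 ± 20.3 CPM against 161 ± 15.5 CPM, a log2 fold change of 0.49 (SE 0.11, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00384). Vegfa, the main endothelial growth factor (chromosome 17, 46016993 to 46032377), was higher at 718.5 ± 176 CPM against 396 ± 23.6 CPM, a log2 fold change of 0.86 (SE 0.15). Without AAV9-hFNDC4 replicate 2, the log2 fold change of Vegfa was 0.65. Fgf1 (chromosome 18, 38838672 to 38929470), a growth factor, was higher at 4.09 ± 0.903 CPM against 1.76 ± 0.442 CPM. Adgrf5, an adhesion receptor (chromosome 17, 43360329 to 43459557), was higher at 9.26 ± 1.72 CPM against 5.07 ± 0.841 CPM. Its log2 fold change of 0.87 was 0.42 with the length correction, which ended the call.

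Among 37 tested HIF1A targets, 14 were higher, 3 lower and 20 did not pass. Ero1a, an oxidase of protein folding, was higher by 1.84 on the log2 scale (SE 0.29), Bhlhe40 by 0.98 (SE 0.13) and Mxi1 by 0.89 (SE 0.14). Without AAV9-hFNDC4 replicate 2, Ero1a was higher by 1.36. The lower members included Tfrc, the transferrin receptor, with a log2 fold change of -1.51 (SE 0.19), and Edn1, endothelin, at 0.00905 against 0.464 CPM. The list as a whole missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0716, and adjusted p = 0.784 with an estimated correlation). It passed without AAV9-hFNDC4 replicate 1 (adjusted p = 0.000418), AAV9-hFNDC4 replicate 3 (0.0201) or AAV9-CTRL replicate 2 (0.0405), without the low-count filter and with the length correction. It did not pass without AAV9-hFNDC4 replicate 2 (adjusted p = 0.189, with the list median at 0.13 in place of 0.35), AAV9-CTRL replicate 1 (0.203) or AAV9-CTRL replicate 3 (0.059), and the range over its alternatives was 0.000418 to 0.784. Of 17 tested glycolysis genes, 9 of whose list are also HIF1A targets, Hk1 was higher by 0.62 (SE 0.12), Hk2 was higher by 1.14 (SE 0.33), Eno3, the muscle enolase, was lower with -0.65 (SE 0.11), and 14 did not pass. The glycolysis list was not called (camera, Benjamini-Hochberg adjusted p = 0.866), and Hk2 lost its call without AAV9-CTRL replicate 2 (adjusted p = 0.095, range 0.00559 to 0.181 over its alternatives), without the low-count filter and with the length correction. Without AAV9-hFNDC4 replicate 2, the log2 fold change of Hk2 was 0.64. Aldoc, an aldolase, had a log2 fold change of 0.68 (SE 0.26) that did not pass and passed in 11 of 15 alternatives, among them without AAV9-CTRL replicate 2 (1.09) and without AAV9-hFNDC4 replicate 1 (0.78).

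Angiogenic ligands and receptors went both ways, with 8 of 26 tested members higher, 4 lower and 14 that did not pass. Nrp2, a VEGF co-receptor, was higher at 394.5 ± 61.8 CPM against 170 ± 32.7 CPM, a log2 fold change of 1.22 (SE 0.15). Notch4 was lower with -2.14 (SE 0.40), and Thbs1, an inhibitor of angiogenesis, had 0 counts in the libraries labelled AAV9-hFNDC4 against 1.42 ± 0.379 CPM, at least 52.6-fold lower. The list was not called (camera, Benjamini-Hochberg adjusted p = 0.434), and its median was positive and its mean negative.

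Heat shock proteins, the chaperones that refold damaged proteins, were lower in 14 of 16 tested members and higher in 0, with a median log2 fold change of -1.32 (camera, Benjamini-Hochberg adjusted p = 1.4e-21, and adjusted p = 0.119 with an estimated correlation). Hspa1b stood at 3.71 ± 1.16 CPM against 2715 ± 437 CPM, a log2 fold change of -9.51 (SE 0.26), and Hspa1a had 4 counts over the 3 libraries against 17894. These 2 copies are nearly identical, so their split is uncertain, and their sum was 3.75 ± 1.17 CPM against 2893 ± 506 CPM, a ratio of 772. Hsph1 was lower with -2.87 (SE 0.18) and Bag3, a co-chaperone, with -2.10 (SE 0.11). Hspb1 had 1 count against 117, a ratio of 130 with a 95% counting interval from 22.9 to 5176.

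Immediate early genes, which respond within minutes to stimulation, were lower in 15 of 22 tested members, with a median log2 fold change of -1.22 (camera, Benjamini-Hochberg adjusted p = 1.83e-15, and adjusted p = 0.113 with an estimated correlation). Fos stood at 3.14 ± 0.413 CPM against 161 ± 34.8 CPM (log2 fold change -5.68, SE 0.20), Fosb was lower with -5.04 (SE 0.24), Egr1 with -2.71 (SE 0.14) and Ier5 with -2.45 (SE 0.10). The 4 higher members were Egr3 by 1.83 (SE 0.23), Nr4a2 by 0.96 (SE 0.17), Fosl2 by 0.65 (SE 0.13) and Myc by 0.44 (SE 0.14). Of 9 tested cardiac stress genes, 7 were lower and 0 higher (camera, Benjamini-Hochberg adjusted p = 0.00148, and adjusted p = 0.251 with an estimated correlation). Acta1, skeletal actin, was lower with -1.79 (SE 0.17), Tnfrsf12a with -1.57 (SE 0.16) and Gdf15 with -0.94 (SE 0.16), while Nppa averaged 0.0101 CPM. In the unfolded protein and integrated stress response, 12 of 21 tested members were lower, among them Creld2 with -1.42 (SE 0.16), Dnajb9 with -1.18 (SE 0.16) and Manf with -1.16 (SE 0.16). The 3 higher members were Trib3 by 1.40 (SE 0.13), Chac1 by 0.60 (SE 0.17) and Ddit3 by 0.49 (SE 0.15), and adjusted over the list alone 6 were higher and 14 lower. That list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0778) and passed without AAV9-hFNDC4 replicate 2 (adjusted p = 0.00938), without AAV9-CTRL replicate 2 (0.002) and without the low-count filter, in a range from 0.002 to 0.784 over its alternatives.

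**Figure D2:**
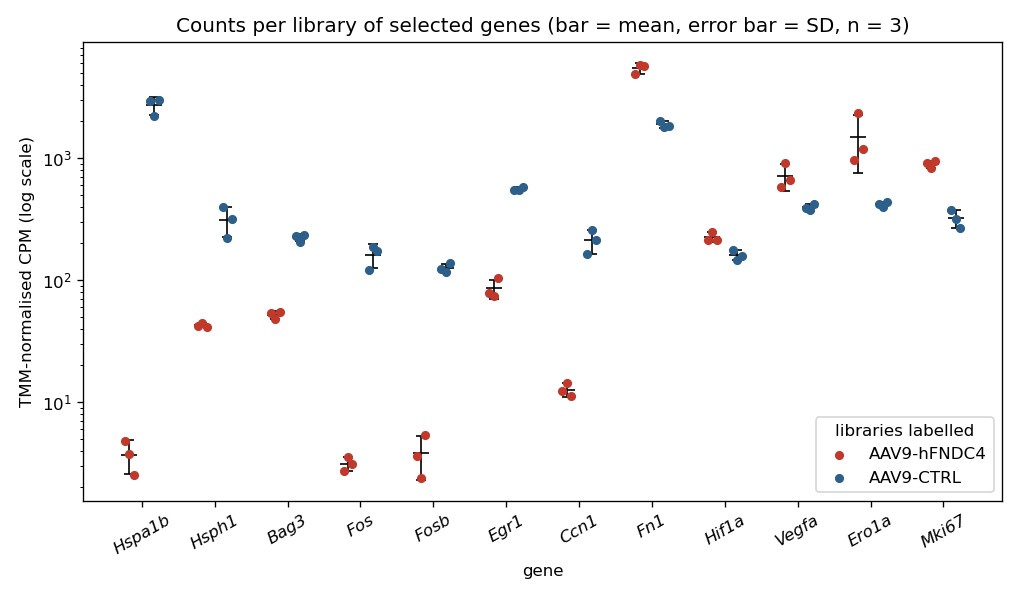
TMM-normalised CPM (log axis) of 12 genes in each of the 6 libraries, in red for those labelled AAV9-hFNDC4 and in blue for AAV9-CTRL, with the mean and SD of each group (n = 3). The points of the groups do not overlap for any of these genes, and Hspa1b stood at 3.71 against 2715 CPM.

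Nuclear genes of oxidative phosphorylation, which encode respiratory chain subunits, were lower in 41 of 44 tested members and higher in 0, with a median log2 fold change of -0.72 (camera, Benjamini-Hochberg adjusted p = 7.8e-14, and adjusted p = 0.426 with an estimated correlation). Ndufb10 stood at 48.4 ± 5.78 CPM against 107 ± 11.5 CPM, and Cox6c at 221 ± 2.82 CPM against 430 ± 45.2 CPM. Across genes, which are not independent replicates, longer transcripts had higher fold changes (Spearman rho 0.327), from a median of -0.48 in the shortest 10% to 0.44 in the longest 10%, and the median of this list was -0.42 with the length correction. Of 13 genes encoded by mitochondrial DNA, ND5 was higher by 1.07 (SE 0.18) and 12 did not pass, among them COX1 at 0.41 (SE 0.20), which passed without the low-count filter and, at 0.68, without AAV9-CTRL replicate 2. Mitochondrial genes took 2.15% to 2.31% of the counts in the libraries labelled AAV9-hFNDC4 and 0.955% to 2.07% in those labelled AAV9-CTRL. The mitochondrial list was not called (camera, Benjamini-Hochberg adjusted p = 0.335) except without AAV9-CTRL replicate 2 (adjusted p = 0.0177, range 0.0177 to 0.864 over its alternatives). Fatty acid oxidation genes split, with 5 of 26 higher and 6 lower (camera, Benjamini-Hochberg adjusted p = 0.744). Lpl, a lipase, was higher by 0.90 (SE 0.11), Acot2 by 1.02 (SE 0.13) and Ppargc1a, a coactivator of mitochondrial genes, by 0.97 (SE 0.14), while Pdk4 was lower with -1.10 (SE 0.13). Antioxidant and NRF2 target genes were lower in 11 of 23 members and higher in 1, Nfe2l2 itself, and adjusted over the list alone 14 were lower and 1 higher. Txn1 was lower with -1.09 (SE 0.10), Gpx1 with -0.84 (SE 0.10) and Sod2 with -0.71 (SE 0.10). The antioxidant list was called (camera, Benjamini-Hochberg adjusted p = 0.00789, and adjusted p = 0.218 with an estimated correlation). With the length correction it was not called (adjusted p = 0.115), with a median of -0.16 in place of -0.45.

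Genes of cell death changed in both directions. Pro-apoptotic genes were lower in 12 of 23 tested members and higher in 4 (camera, Benjamini-Hochberg adjusted p = 0.0996). Bax, a pore-forming BCL2 family member, was lower with a log2 fold change of -0.91 (SE 0.10), Cycs (cytochrome c) with -1.20 (SE 0.13), Bak1 with -0.81 (SE 0.10) and Bcl2l11 with -0.95 (SE 0.13), while Bbc3, Fadd, Bmf and Casp9 were higher. Anti-apoptotic genes were lower in 8 of 17 members and higher in 2, and in 9 and 2 adjusted over the list alone. Bag3, Ier3 with -1.83 (SE 0.23) and Akt1 with -0.57 (SE 0.09) were lower, and Xiap, a caspase inhibitor, was higher by 0.98 (SE 0.12) with Bcl2 by 0.86 (SE 0.16). This list was called lower (camera, Benjamini-Hochberg adjusted p = 0.0394, and adjusted p = 0.251 with an estimated correlation). It lost the call without AAV9-hFNDC4 replicate 3 (adjusted p = 0.0566), AAV9-CTRL replicate 1 (0.0756) or AAV9-CTRL replicate 2 (0.069), and with the GC correction, in a range from 0.000676 to 0.251 over its alternatives. The pro-apoptotic and anti-apoptotic lists had close medians of -0.29 and -0.32, and fry called both lower (Benjamini-Hochberg adjusted p = 0.000676 each). Bag3 is also a member of the heat shock list. Of 12 pyroptosis and necroptosis genes, Aim2 and Casp4 were higher by 0.52 (SE 0.09) and 0.76 (SE 0.16), and Ripk3 and Nlrp3 lower with -0.70 (SE 0.10) and -2.02 (SE 0.55), the last -2.80 without AAV9-hFNDC4 replicate 2. The list was not called (camera, Benjamini-Hochberg adjusted p = 0.998), with a positive median and a negative mean.

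Inflammatory cytokines and chemokines were lower in 11 of 23 tested members and higher in 2 (camera, Benjamini-Hochberg adjusted p = 0.0138, and adjusted p = 0.365 with an estimated correlation). Csf3, the granulocyte growth factor, stood at 0.0992 ± 0.0399 CPM against 2.48 ± 0.128 CPM, Il11 at 0.991 ± 0.319 against 6.82 ± 1.30 CPM, Ccl2 at 63.2 ± 17.1 against 151 ± 22.5 CPM and Tnf at 3.15 ± 0.779 against 9.31 ± 2.13 CPM. The higher members were Nos2, inducible nitric oxide synthase, and Csf1. With the length correction the inflammatory list lost its call (camera, Benjamini-Hochberg adjusted p = 0.0539), with a median of -0.64 in place of -0.84. Interferon response genes were higher in 8 of 25 members, with Oas3 at 15.4 ± 0.954 CPM against 7.67 ± 1.64 CPM, Ifi44 by 1.80 (SE 0.34), Ifih1 by 0.95 (SE 0.20) and Oas2 by 0.79 (SE 0.16), while Oasl1 and Bst2 were lower. That list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0996) and passed without AAV9-CTRL replicate 2 (adjusted p = 0.0386), without the low-count filter and with the length correction, in a range from 0.0203 to 0.663 over its alternatives. Among markers of immune cells, most lay near the detection limit. Of 7 tested neutrophil markers, 4 were lower and Lcn2, a secreted siderophore-binding protein, was higher by 0.92 (SE 0.25) (camera, Benjamini-Hochberg adjusted p = 0.297). Of 13 monocyte and macrophage markers, Cd68 was lower with -1.25 (SE 0.14), Itgam had 0 counts against 1.69 ± 0.163 CPM, at least 62.2-fold lower, in a gene that shares 70% of its exon bases with another, and Mertk was higher by 0.73 (SE 0.17). That list was not called (camera, Benjamini-Hochberg adjusted p = 0.53).

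Extracellular matrix genes split evenly, with 8 of 24 tested members higher and 8 lower, and 9 and 8 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.866). Fn1, fibronectin, was higher at 5467 ± 533 CPM against 1890 ± 111 CPM (log2 fold change 1.53, SE 0.12) and Col3a1 by 0.91 (SE 0.11). Ccn1, a matricellular protein induced by stress, was lower at 12.6 ± 1.61 CPM against 212 ± 47.0 CPM, and Tgfb2 at 0.362 ± 0.371 CPM against 11.8 ± 3.19 CPM, a log2 fold change of -5.01 (SE 0.50) that was -6.26 without AAV9-hFNDC4 replicate 3. Among fibroblast markers, 6 of 13 were higher, with Pdgfra by 1.21 (SE 0.21), Ddr2 from 298.5 ± 67.9 to 595 ± 118.5 CPM and Lamc1 by 0.84 (SE 0.14), and 3 were lower, Pcolce, Dpt and Mfap5 (camera, Benjamini-Hochberg adjusted p = 0.335). Of 5 tested mural cell markers, Pdgfrb was higher by 1.05 (SE 0.10), Cspg4 by 0.72 (SE 0.12) and Mylk by 0.62 (SE 0.12), the last not with the length correction. Notch3 was lower with -2.56 (SE 0.64), which was -3.74 without AAV9-hFNDC4 replicate 3, as was Tagln with -1.80 (SE 0.63), and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.225). The median and the mean differed in sign in the matrix, fibroblast and mural lists.

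Proliferation genes also went both ways, with 6 of 28 members higher and 9 lower (camera, Benjamini-Hochberg adjusted p = 0.789, with a median below and a mean above 0). Mki67 was higher at 897 ± 59.3 CPM against 320 ± 53.5 CPM (log2 fold change 1.49, SE 0.13), as were the mitotic kinesins Cenpe by 0.90 (SE 0.10) and Kif11 by 0.78 (SE 0.10), while Cdc20, an activator of anaphase, was lower with -0.70 (SE 0.12). Circadian clock genes were higher in 11 of 15 members and lower in 1, Cry1, with a median of 0.64 (camera, Benjamini-Hochberg adjusted p = 0.00204, and adjusted p = 0.27 with an estimated correlation). Per3 was higher by 1.38 (SE 0.20), Bhlhe41 by 0.99 (SE 0.16), Per2 by 0.84 (SE 0.11) and Per1 by 0.58 (SE 0.10). Of the 10 tested endothelial markers, Aqp1 and Fabp4 were lower with -0.52 (SE 0.10) and -0.69 (SE 0.19), and 8 did not pass (camera, Benjamini-Hochberg adjusted p = 0.434). Of 16 tested cardiomyocyte markers, 3 were higher and 7 lower (camera, Benjamini-Hochberg adjusted p = 0.563), among them Gata4 at 12.5 ± 1.33 against 7.11 ± 0.282 CPM and Tnnt2 at 38.1 ± 0.669 against 51.7 ± 1.71 CPM.

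Lists of other tissues served as a check of the material. Of 6 tested skeletal muscle genes, Ampd1, AMP deaminase, was lower at 0.127 ± 0.0700 CPM against 27.2 ± 6.45 CPM and Tnni2 with -1.46 (SE 0.40), while the myosins Myh1, Myh2 and Myh4 averaged at most 0.00477 CPM. This list was called (camera, Benjamini-Hochberg adjusted p = 0.00762, and adjusted p = 0.218 with an estimated correlation), and Tnni2 lost its call with the length correction. Of 6 adipocyte genes, Pck1 had 0 counts against 1.90 ± 0.566 CPM, at least 69.2-fold lower, and Adipoq had 1 count against 81, a ratio of 90.0 with a counting interval from 15.7 to 3596 (camera, Benjamini-Hochberg adjusted p = 0.101). The other 6 lists had fewer than 5 tested members and no list test. In the atrial list (4 tested) Nr2f2 was higher by 0.93 (SE 0.13). In the red blood cell list (3 tested) Slc4a1 had 0 counts against 0.588 ± 0.202 CPM, at least 21.8-fold lower, and Bpgm was lower with -0.40 (SE 0.15). The call of Bpgm was lost in 9 of 15 alternatives, among them without any single library other than AAV9-hFNDC4 replicate 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0482, range 0.0392 to 0.165 over its alternatives). Msln was lower with -0.70 (SE 0.11) among 2 tested epicardial and mesothelial genes, and Cd79a was lower with -3.19 (SE 0.87) among 3 tested lymphocyte genes. Cd79a stood at -5.31 without AAV9-hFNDC4 replicate 1, and its call was lost without AAV9-CTRL replicate 3 (Benjamini-Hochberg adjusted p = 0.0575, range 0.00097 to 0.0575 over its alternatives). The Schwann cell genes S100b (50.5 ± 1.37 against 56.0 ± 15.0 CPM) and Mbp (7.24 ± 0.559 against 7.03 ± 2.02 CPM) and the lung epithelial gene Napsa (65.2 ± 5.54 against 75.3 ± 16.4 CPM) did not pass.

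**Figure D3:**
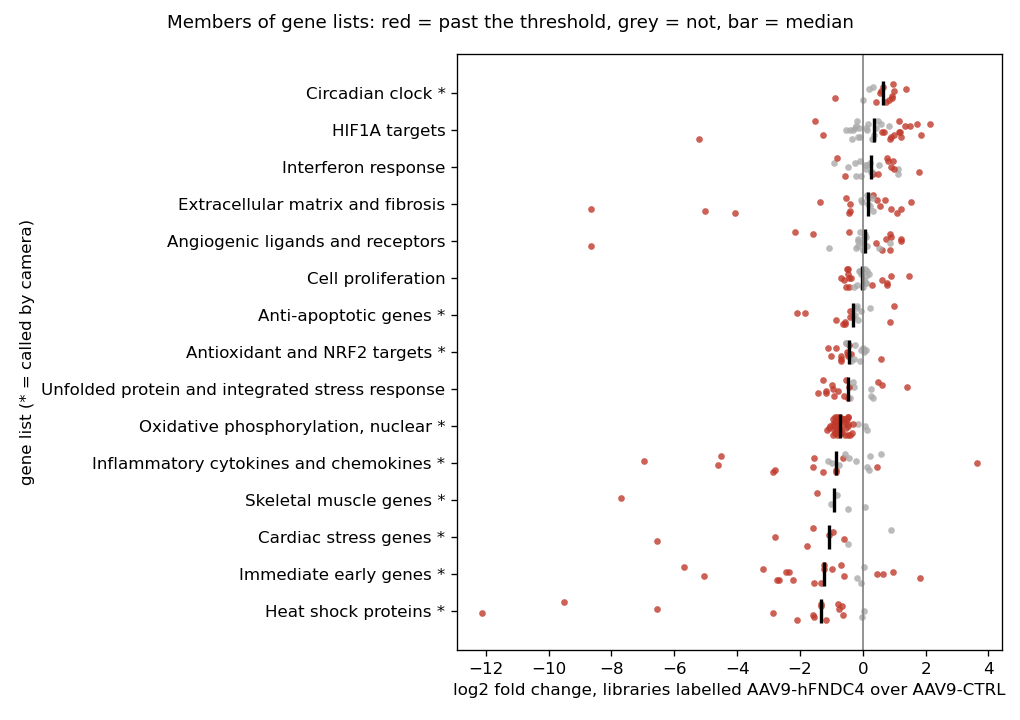
Log2 fold change, libraries labelled AAV9-hFNDC4 over AAV9-CTRL, of the tested members of 15 gene lists, in red past the threshold and in grey not, with the list median as a bar and lists called by camera marked by a star. Members with few or 0 counts in a group are drawn at fitted values, which are no bounds, and the heat shock median lay at -1.32.

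Across the 27 tested lists, camera called 8 lower and 1 higher, of which 0 held with an estimated correlation (4 lists at an unadjusted p under 0.05), and fry called 14. The counts adjusted over the list alone equalled those over all genes tested except in the 4 lists where both are given. Median, mean and camera direction differed in sign in 7 lists, glycolysis included with a median of -0.12 and a mean of 0.06. Camera called none of the 7, but fry called the mural cell list among them (Benjamini-Hochberg adjusted p = 0.00467). Placing members with 0 counts in a group at their bounds moved no list median.

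The largest increases among the named genes were in Igfbp5, an insulin-like growth factor binding protein (chromosome 1, 72858065 to 72874865), at 8.73 ± 2.13 CPM against 0.585 ± 0.205 CPM, a log2 fold change of 3.89 (SE 0.31). Next came Kctd16 (3.66, SE 0.50), Nos2 (3.64, SE 0.71), Nfe2 (3.27, SE 0.41) and Sspo (3.23, SE 0.48). Smaller increases were those of Mboat2 (2.78, SE 0.70), the antisense transcript Nckap5los (2.78, SE 0.45), Cask (2.67, SE 0.48), Neb (2.53, SE 0.46), Pkhd1l1 (2.52, SE 0.43), Gem (2.45, SE 0.47) and the cholesterol exporter Abca1 (2.38, SE 0.26). AAV9-hFNDC4 replicate 2 carried part of several of these, since without it the log2 fold change was 2.86 for Kctd16, 2.56 for Nos2, 2.42 for Sspo, 1.83 for Gem and 1.78 for Mboat2, which then missed the threshold (Benjamini-Hochberg adjusted p = 0.0553, range 1.41e-07 to 0.0553 over its alternatives). Nckap5los shares 31.1% of its exon bases with Nckap5l on the other strand and stood at 3.54 without AAV9-CTRL replicate 2, and Nos2 missed the threshold without the low-count filter.

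Besides Hspa1a and Hspa1b on chromosome 17 (34969359 to 34972156 and 34956429 to 34959238), the decreases named by the rule, among genes with a mean of at least 1 CPM, included genes with 0 or 1 counts over the 3 libraries labelled AAV9-hFNDC4, whose order of size is not known. Rasl11a, a small GTPase (chromosome 5, 146845071 to 146847726), stood at 6.43 ± 0.883 CPM in the libraries labelled AAV9-CTRL and was at least 235-fold lower. Ccdc81 was at least 136-fold lower, Etv2, an ETS transcription factor of early endothelial development, at least 125-fold, Zdbf2 at least 117-fold, Mgl2 at least 112-fold and Fam71e2 at least 74.4-fold. With 1 count each, Colec11 gave a ratio of 626 (95% counting interval 112 to 24780), Nacad 359 (63.9 to 14210), Tcfl5 314 (55.9 to 12460) and the Notch ligand Dll1 310 (55.2 to 12280). Of their exon bases, Dll1 shared 17.4%, Tcfl5 10.5%, Hspa1a 19.0%, Kctd16 12.6%, Bhlhe41 13.7%, Bak1 10.7% and Napsa 16.7% with a gene on the other strand, and Bax 22.1% with a gene on its own strand, so reads of these genes are uncertain. In all, 50 genes had at most 3 counts over the libraries labelled AAV9-hFNDC4 and at least 1 CPM in those labelled AAV9-CTRL, and 0 genes showed the opposite.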

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

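Apart from the corrections for transcript length and GC content, which were chosen after the data had been seen, these alternatives were fixed before the data were examined. The counts of 3240 higher and 3668 lower genes stayed within 1.5 times under all alternatives except an unadjusted p under 0.05 with an absolute log2 fold change above 1, which gave 1117 and 1120, since it leaves out smaller changes. Leaving out 1 library gave 2299 to 3501 higher and 2974 to 3896 lower genes. The length correction, with 13392 genes tested, gave 2684 and 3326, of which 4962 were also called without it, and 129 genes called without it changed in sign. Camera called 9 lists, and 8 to 12 without 1 library, but 0 with an estimated correlation (4 at an unadjusted p under 0.05) and 14 by fry, which does not compare a list with other genes; the cause was not tested. The replicate numbers did not pair the samples (deviations of same-numbered libraries correlated at -0.0872, -0.202 and -0.0585, and 0 of 3 libraries matched best with their number). With the replicate block, 2663 genes were higher and 3080 lower, 10 lists were called, and the HIF1A target list passed (Benjamini-Hochberg adjusted p = 0.00172, against 0.000418 to 0.784 over its alternatives). Across the alternatives in which each of the 148 named genes was tested, 2155 results stayed on the same side of the threshold with the same direction, 18 calls were lost, 19 were gained and 0 reversed. Most named genes were chosen from these same data by a large change or a small p, which favours such stability, so it does not speak for genes at large. Most detected immune and muscle markers stood near or under 1 CPM, where low counts limit what could be seen of changes. At 32975817 or more counts per library, depth does not account for the low levels themselves.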

Other observations

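The gene groups in the next paragraph, and all tests in this part except those of Y chromosome genes, of single libraries, of length and GC trends and of other splits of the libraries, were chosen after results had been seen, as were the genes named there; the list of Y chromosome genes and the length and GC corrections were themselves added after other data had been seen, but before the values that their tests measure. The criteria of 2 tests were also changed after their values had been seen. For loss of cardiomyocytes, a first version asked what share of 28 endothelial and leukocyte markers reached 1 CPM, and the value (32.1%) lay between its bounds of 25% and 50%, so a median with a bound of 10 CPM replaced it. For length, the bound set in advance was a median below -0.4, which the value passes only narrowly and its interval does not, so the criterion became an interval below -0.2 with the list still called.

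Beyond the lists fixed in advance, subunit genes of the proteasome, the cytosolic ribosome and the CCT chaperonin were lower together in the libraries labelled AAV9-hFNDC4. All 31 tested proteasome subunits were lower, with a median log2 fold change of -1.05, among them Psmb5 at 40.7 ± 2.09 CPM against 93.6 ± 5.67 CPM and Psma1 at 102 ± 5.81 against 213.5 ± 23.0 CPM (n = 3 each). All 84 tested cytosolic ribosomal protein genes were lower (median -0.82), as were all 8 subunits of the CCT chaperonin, which folds actin and tubulin (median -0.70). Of 18 tested p53 targets, 10 were lower and 1 higher, with the cell cycle inhibitor Cdkn1a at 73.2 ± 8.74 against 206 ± 17.2 CPM and Mdm2 at 80.1 ± 8.97 against 189 ± 24.7 CPM. Of 28 replication-dependent histone genes and relatives, 20 were lower and 1 higher, with a median of -2.55 at levels mostly near 1 CPM. These 5 groups were called by camera (Benjamini-Hochberg adjusted p = 1.62e-28 to 0.000295), with adjusted p = 0.192 for each with an estimated correlation. The groups were picked after results had been seen, so these p-values are no support for the pattern. Cholesterol synthesis genes, with 4 of 19 higher and 4 lower, were not called (camera, Benjamini-Hochberg adjusted p = 0.907). With the length correction, the medians of proteasome, ribosomal and CCT genes were -0.76, -0.44 and -0.54; the histone genes could not be checked for length, since 1 of 28 had a matched length.

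For the near absence of most cardiac transcripts, which goes against the tissue label, a few genes taking up most counts are argued against, since the 10 most abundant genes took at most 5.18% of the counts in any library. For loss of cardiomyocytes from injured hearts, markers of the endothelial and leukocyte cells that would remain had a median of 0.184 CPM over 28 genes. The upper end of its 95% interval over these chosen markers was 1.18 CPM, with Cdh5 at 0.0283 and Ptprc at 0.0910 CPM. Aqp1 (265 CPM), Eng (224), Fabp4 (166) and Coro1a (10.2) stood far above that median. Most of these levels are low for such cells, but the bound of 10 CPM was set after they had been seen, so the test gives no verdict. A source in cells of 1 mesenchymal type stays open: 86.7% of 15 mesenchymal markers reached 1 CPM in at least 3 libraries, but the list was written after Fn1, Vim and Col1a1 had been seen to be abundant, so this share is no support for it, and the 6.98% of pooled leukocyte, epithelial, hepatocyte, neuron, myoblast and pluripotent markers leaves out lists with higher shares. Cardiac fibroblasts stay open too, since 13 of 18 fibroblast markers (72.2%) reached 1 CPM in at least 3 libraries, led by Pcolce (492.5 CPM), Ddr2 (455) and Lamc1 (404), while Dcn, Lum and Tcf21 averaged at most 0.0432 CPM. Of the monocyte and macrophage markers, 11 of 22 reached 1 CPM as well, led by Spp1 (2963 CPM). Among those that did not, C1qa averaged 0.032, Adgre1 0.0283 and Cd163 0.0051 CPM. Whether the source lacks a Y chromosome, against the title's male mice, stays open, because only Eif2s3y (at most 0.0303 CPM in any library) could be read and the other Y genes of the list were not analysed here.

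Of other lineages, 4 of 9 osteoblast markers (Runx2 60.4 CPM), 4 of 7 chondrocyte, 5 of 9 astroglial (S100b 53.2 CPM) and 1 of 5 melanocyte markers reached 1 CPM in at least 3 libraries, and Xist averaged 0.636 CPM.

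The differences in heat shock and immediate early genes had a joint median log2 fold change of -1.28 over both lists. A single library as the source is argued against, since the median was still -1.21 with the library left out that moved it nearest to 0. A proteotoxic stress in the material labelled AAV9-CTRL stays open: the proteasome median of -1.05 (-0.76 with the length correction) does not exclude it, but is no support for it either, since this group was picked after it had been seen to be lower. A difference in handling or library batch cannot be told apart from the vector, since the labels give no batch. The component that separates the labels holds 70.6% of the variance, which does not tell them apart. The vector itself stays open and untested, and these values give no evidence on FNDC4 in heart tissue while the source of the material is unsettled.

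The decrease of oxidative phosphorylation genes ran with a trend of fold change on transcript length. The list's transcripts are short (median 1298 bases against 3205 for all tested genes), and removing the trend moved its median from -0.72 to -0.42 (upper end of the 95% interval -0.33), with the list still called (camera, Benjamini-Hochberg adjusted p = 9.05e-06). The call rests on the preset correlation, since without the length correction it had an adjusted p = 0.426 with an estimated correlation, and the range over its alternatives was 1.81e-19 to 0.426 (camera, Benjamini-Hochberg). Length bias may account for part of the decrease. Whether it is the whole source stays open, since the criterion was changed after the value had been seen. The interval also treats the members of the list as independent. The median of -0.69 after removal of the GC trend argues against GC bias as the whole source. The vector and a batch or handling difference between the labels stay open and untested for the rest.

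The count of changed genes was also set against other groupings of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes, the real split with 6908, and the highest of the others gave 0 (edgeR quasi-likelihood, with at most 882 genes at an unadjusted p under 0.05). With 10 splits, no share under 0.05 can be reached.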
